A study of Mus musculus with 15 samples.

How the data were processed

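RNA from 3T3-L1 cells of 5 groups, with 3 libraries each, was extracted with a column kit and made into strand-specific TruSeq RNA libraries per the labels. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.19, trimmed with Trimmomatic, aligned to the mouse genome GRCm38.p5 with STAR 2.5.4b, assigned to genes with featureCounts and tested with edgeR. The deposited values are raw counts of reads per gene, 1 column per library, with 25700 Ensembl gene identifiers. The values were checked to be non-negative whole numbers. Of the identifiers 25587 were matched to a symbol and position in GENCODE vM21 (GRCm38), and 113 were kept without a symbol. The annotation release used for counting, the strand setting of counting, and the handling of reads that align to several places are not given in the sources used here. Library totals ran from 10748668 to 26003871 counts, with WT day 0 the deepest group. The labels do not say whether the replicates are separate cultures, so p-values measure only the spread between these samples. Replicate numbers were checked for pairing between groups and did not pair the samples, so replicates were treated as unpaired. Deviations from the group mean correlated at -0.723 to 0.125 for the same number. They were shared across numbers in WT, with 0.715 for day 0 replicate 3 and day 6 replicate 1. Day 0 replicate 1 was at 0.48 and 0.476 with day 6 replicates 2 and 3. The structure went with trends in GC content and log transcript length. Deviations correlated with these at -0.64 and 0.58 in WT day 0 replicate 3 and -0.56 and 0.56 in WT day 6 replicate 1. The signs were opposite in WT day 0 replicate 1, at 0.42 and -0.67. They were likewise opposite in WT day 6 replicate 2 (0.29 and -0.48) and replicate 3 (0.58 and -0.42). WT day 0 replicate 2 was at 0.06 and 0.58. What gave rise to these trends was not tested. No sequencing batch is given in the labels.

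Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 12279. Library sizes were scaled with TMM, and a quasi-likelihood model with 1 term per group was fitted to all 15 libraries (common biological coefficient of variation 15.96%). The comparisons were day 6 against day 0 in WT and in MIGA2-KO, MIGA2-KO against WT at day 0 and at day 6, MIGA2-GFP against WT at day 6, and the difference between the lines in the change over time. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes tested within a comparison, with a threshold of 0.05. Levels are CPM as mean ± SD of 3 libraries. The ± beside a log2 fold change is the SE implied by the quasi-likelihood F test. It is the absolute log2 fold change divided by the square root of F. Where a group had no count for a gene, the fold is a bound against a floor of 3 counts over the group. With 1 to 3 counts the ratio of counts is given with its exact 95% interval. Fitted log2 fold changes of such genes depend on the prior count. Intervals and floors cover counting error only.

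Before the data were examined, 32 gene lists, the comparisons, the model, the thresholds, the rule for naming genes and most alternatives were fixed. The lists cover adipogenic regulators, adipocyte markers and adipokines, lipid droplet proteins, de novo lipogenesis, triacylglycerol synthesis, lipolysis, cholesterol synthesis and uptake, mitochondrial fatty acid oxidation, the TCA cycle and pyruvate entry, the nuclear-encoded respiratory chain and ATP synthase, mitochondrially encoded mRNAs, mitochondrial dynamics and organelle contact proteins, the unfolded protein response, integrated stress response targets, mitochondrial chaperones and proteases, peroxisomal proteins, glycolysis, insulin signalling, thermogenic genes, preadipocyte markers, extracellular matrix, myofibroblast and contractile genes, the cell cycle, p53 targets, the interferon response, chemokines and acute phase genes, and markers of macrophages, skeletal muscle, osteoblasts, chondrocytes, epithelium and endothelium. The endothelial list had fewer than 3 tested members and was not tested. List sizes given in the text count tested members only. The other 31 lists were compared with the remaining genes by camera in limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the 186 tests of 31 lists in 6 comparisons. The calls were recomputed with a correlation estimated from the data, under which 8, 9, 2, 5, 0 and 6 lists were called in the 6 comparisons. They were also set beside fry, which tests whether the genes of a list move, on balance, one way and compares them with no other genes. Named genes are Miga2 and Miga1, the 8 largest changes in each direction, and up to 4 members per list with the smallest adjusted p (2 with the highest CPM where none passed). The largest changes were taken among genes with a symbol and no pseudogene annotation, with an adjusted p under 0.05, at least 5 CPM in a compared group and, except for the difference between lines, no overlap between the 3 libraries of each group. A member named in 1 comparison was followed through the others. Some genes that this rule selects are not reported here.

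Data were simulated from the mean level and dispersion of each of 12279 genes. The share of 2-fold changes found was 73.1% for WT over time, 70.1% for MIGA2-KO over time, and 67.2% for MIGA2-KO against WT at day 0. It was 62.7% at day 6, 65.7% for MIGA2-GFP against WT, and 28.4% for the difference between lines. For 4-fold changes these shares were 97%, 93.9%, 98.5%, 90.9%, 87.9% and 86.4%, and false calls made up 3.4% to 5.9% of all calls. A simulated list of raised genes was found by camera, and 0 of 50 lists without a simulated change were called. Genes were simulated independently of each other, so this does not test the preset correlation on which the list calls depend. In the simulation of single genes, 66 or 67 genes were changed at each fold, against 3346 to 7956 called in the real comparisons. The adjustment of p-values is stricter when few genes change, so the shares found need not hold for the real comparisons. Each gene was simulated with the same spread in all groups and without a trend with GC content or length. The share of false calls therefore need not hold for the real libraries either.

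Alternatives were RLE size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter on low counts, a filter of 1 CPM in at least 3 libraries, a replicate block, a fit to only the samples compared, leaving out each library in turn, camera with an estimated correlation and fry, and for the correlation of fold changes a minimum of 10 CPM. Chosen after seeing the data were a correction for GC content and transcript length with smooth terms per library, leaving out replicate 1 of WT day 0, of WT day 6 and of MIGA2-KO day 6 together, thinning WT day 0 to the depth of WT day 6, and leaving out chromosome 8. No library was left out of the values reported. The library labelled MIGA2-KO day 6 replicate 1 was kept although its Miga2 level lay far from the others, since nothing in the labels sets it apart. The correlation between the day 6 differences of MIGA2-KO and MIGA2-GFP was set beside 50 simulated data sets in which the shared WT libraries were the sole link.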

Results

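Gene expression was measured by RNA sequencing in 3T3-L1 cells, a mouse preadipocyte line that turns into lipid-storing fat cells when a confluent culture receives dexamethasone, IBMX and insulin. The 15 libraries formed 5 groups of 3. Wild-type (WT) cells and cells labelled as depleted of MIGA2 (MIGA2-KO) were sampled at day 0, when the differentiation medium was added, and at day 6, and cells labelled as overexpressing MIGA2 fused to green fluorescent protein (MIGA2-GFP) were sampled at day 6. MIGA2, mitoguardin 2, is a protein of the outer mitochondrial membrane. The comparisons ask how the transcriptome changes during differentiation, and how it differs in cells labelled as depleted of MIGA2 or as overexpressing it. MIGA2-GFP cells at day 0 are not among the samples, so the change over time in that line was not measured. Total counts per library ran from 19625147 to 26003871 in WT at day 0, 12139151 to 12355905 in WT at day 6, 11867305 to 12619058 in MIGA2-KO at day 0, 10956827 to 12151824 in MIGA2-KO at day 6, and 10748668 to 13443736 in MIGA2-GFP. Each total comes from 25700 genes, of which 12279 had enough counts to be tested.

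Miga2 mRNA (ENSMUSG00000026858, GRCm38 chromosome 2: 30364233 to 30385521, forward strand) was not lower in MIGA2-KO than in WT cells at either day and was not higher in MIGA2-GFP than in WT cells. It stood at 15.64 ± 2.06 CPM (the count scaled to the TMM-adjusted library total, mean ± SD, n = 3) in WT at day 0, 162.1 ± 18.4 in WT at day 6, 20.37 ± 2.83 in MIGA2-KO at day 0, and 159.8 ± 5.2 in MIGA2-GFP at day 6. In MIGA2-KO at day 6 the 3 libraries held 925.3, 74.5 and 70 CPM, so the library labelled MIGA2-KO day 6 replicate 1 carried more Miga2 mRNA than any other library of the series. The rise over time passed in WT cells (log2 fold change 3.37 ± 0.74 SE, adjusted p = 0.00102 in edgeR quasi-likelihood) and in MIGA2-KO cells (4.13 ± 0.77, adjusted p = 0.000487, and 1.83 without the library labelled MIGA2-KO day 6 replicate 1). MIGA2-KO against WT gave 0.38 ± 0.71 at day 0 (adjusted p = 0.708, edgeR) and 1.14 ± 0.67 at day 6 (adjusted p = 0.157, edgeR). The sign at day 6 rests on the library labelled MIGA2-KO day 6 replicate 1: without it Miga2 was lower in MIGA2-KO, with a log2 fold change of -1.16 that passed. MIGA2-GFP against WT gave -0.02 ± 0.67 (adjusted p = 0.985, edgeR). The paralogue Miga1 (ENSMUSG00000054942, chromosome 3: 152273849 to 152340407, reverse strand) was higher in MIGA2-GFP than in WT, at 4.92 ± 0.643 against 1.22 ± 0.519 CPM (log2 fold change 2.00 ± 0.37, adjusted p = 0.00111, edgeR), and passed in no other comparison. Counts per gene do not show whether Miga2 mRNA in MIGA2-KO cells can still be translated. Whether reads of the MIGA2-GFP construct were counted for Miga2 is not given in the sources used here.

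**Figure D1:**
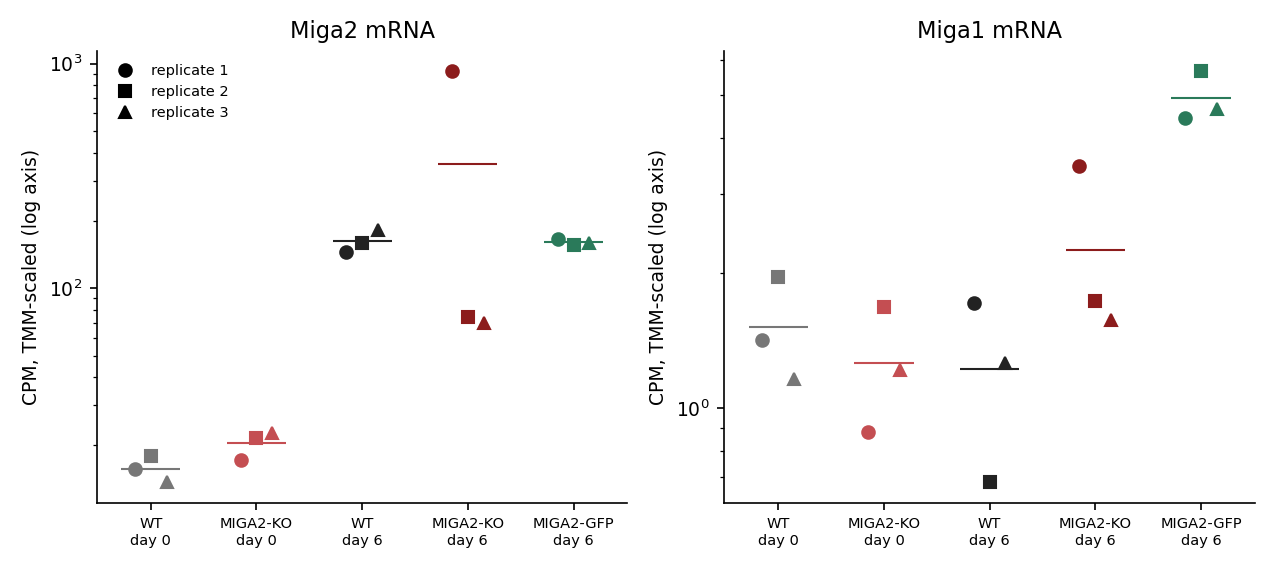
Miga2 and Miga1 mRNA in CPM on a log axis, 1 point per library, with a line at the mean of each group of 3. The library labelled MIGA2-KO day 6 replicate 1 lies at 925.3 CPM of Miga2, above the other 14 libraries.

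Replicates were closest in MIGA2-KO at day 0 and in MIGA2-GFP, where the correlation of log2 CPM across genes lay between 0.9931 and 0.995. It lay between 0.9657 and 0.993 in WT at day 0, 0.9694 and 0.9861 in WT at day 6, and 0.9748 and 0.9918 in MIGA2-KO at day 6, and in each of these 3 groups replicate 1 stood apart from the other pair. Genes are not independent replicates, so these correlations carry no test. Spread relative to counting error, as chi-square per degree of freedom between 2 libraries, differed far more. It was 1.722 to 2.848 in MIGA2-KO at day 0 and 1.743 to 1.913 in MIGA2-GFP. In WT it was 20.95 to 132.2 at day 0 and 9.669 to 68.43 at day 6, and in MIGA2-KO at day 6 2.229 to 37.69. The fit shares its estimate of spread across the groups, so p-values of comparisons with WT may be too small. Transcripts of the 3 replicates also differed in the share taken by mitochondrially encoded genes, which was 2.07%, 2.95% and 3.44% in WT at day 0, and 12.55%, 8.07% and 7.06% in WT at day 6. The share was 4.69% to 4.77% in MIGA2-KO at day 0, 7.73% to 8.78% in MIGA2-KO at day 6, and 8.13% to 8.28% in MIGA2-GFP. The first principal component held 70.3% of the variance of log2 CPM and the other, PC2, 12.6%.

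In WT cells, genes of the fat cell rose within 6 days, some of them from no count or a few counts at day 0. Adipoq, the gene for the hormone adiponectin (ENSMUSG00000022878, chromosome 16: 23146536 to 23158028, forward strand), went from 0.0226 CPM, or 2 counts over the group, to 6751 ± 831 CPM (SD, n = 3), a ratio of 252000 with a 95% counting interval of 69800 to 2080000. Cfd, which encodes adipsin, had no count at day 0 and 9613 ± 4180 CPM at day 6, at least 240000-fold higher against a floor of 3 counts over the group. Fabp4, a fatty acid carrier, rose from 29.72 ± 8.68 to 15720 ± 2710 CPM. Genes near 0 at day 0 also included Retn, for resistin (at least 32600-fold higher), Cyp2e1 (at least 10800-fold), Slc2a4, for the insulin-responsive glucose transporter (at least 5230-fold), and Plin1, for a lipid droplet coat protein (ratio 41700, 95% counting interval 7480 to 1650000). All 20 adipocyte markers and adipokines rose, 20 also adjusted over the list alone, with a median log2 fold change of 8.81, or 8.39 with genes at 0 set to their bound (camera adjusted p = 4.13e-31).

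The master regulators of adipogenesis rose with them. Pparg (ENSMUSG00000000440, chromosome 6: 115360951 to 115490399, forward strand) went from 14.53 ± 1.14 to 294.8 ± 0.887 CPM (log2 fold change 4.34 ± 0.094, adjusted p = 9.82e-14 in edgeR quasi-likelihood), and Cebpa (ENSMUSG00000034957, chromosome 7: 35119293 to 35121928, forward strand) from 5.669 ± 0.643 to 209.4 ± 15.7 CPM (5.21 ± 0.23). Of 19 adipogenic regulators 12 rose and 3 fell (15 adjusted over the list alone, median 1.67, camera adjusted p = 3e-06). Of 23 genes of de novo lipogenesis, 19 rose and 2 fell (21 adjusted over the list alone), with a camera adjusted p of 1.47e-07 and adjusted p = 0.145 with an estimated correlation. Fasn, for fatty acid synthase, went from 196.8 ± 26.6 to 1692 ± 276 CPM. Of 21 genes of triacylglycerol synthesis 16 rose and 3 fell (19 adjusted over the list alone), with a camera adjusted p of 8.45e-08 and adjusted p = 0.0656 with an estimated correlation. Agpat2, for an acyltransferase of this pathway, was at a log2 fold change of 5.69 ± 0.19. All but 1 of 17 lipolysis genes rose (16 adjusted over the list alone, median 6.48, camera adjusted p = 6.99e-17). Lipe, for hormone-sensitive lipase, was at a log2 fold change of 6.53. Of 18 lipid droplet proteins 12 rose and 2 fell (14 adjusted over the list alone), with a camera adjusted p of 3.16e-06 and adjusted p = 0.0698 with an estimated correlation. Fitm2, which acts in droplet formation, stood at 4.77 ± 0.10.

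Mitochondrial and peroxisomal genes rose broadly in WT cells. All 25 genes of the TCA cycle and pyruvate entry rose (25 adjusted over the list alone, median 1.8, camera adjusted p = 1.41e-20). So did 20 of 21 genes of mitochondrial fatty acid oxidation, with 1 lower (21 adjusted over the list alone, median 1.92, camera adjusted p = 9.17e-14). Acadm, for medium-chain acyl-CoA dehydrogenase, was at a log2 fold change of 4.23 ± 0.093. Of 75 nuclear genes of the respiratory chain and ATP synthase 73 rose (75 adjusted over the list alone), with a median of 1.76 (camera adjusted p = 3.4e-14, adjusted p = 0.385 with an estimated correlation). Of the 13 mitochondrially encoded mRNAs 8 were tested, and all 8 rose (8 adjusted over the list alone, camera adjusted p = 0.000259, adjusted p = 0.173 with an estimated correlation). mt-Nd1 rose by 2.52 ± 0.13. Of 32 peroxisomal genes 27 rose and 2 fell (29 adjusted over the list alone, median 1.37, camera adjusted p = 1.2e-12). Pex11a, for a factor in peroxisome division, was at 4.06. Mitochondrial chaperones and proteases rose in 13 of 14 genes (14 adjusted over the list alone, median 1.29, camera adjusted p = 8.39e-05, adjusted p = 0.173 with an estimated correlation). Of 31 genes of mitochondrial dynamics and organelle contacts 18 rose and 3 fell (21 adjusted over the list alone, camera adjusted p = 0.014, adjusted p = 0.0835 with an estimated correlation). Rises in the lists for the unfolded protein response (16 of 25 up, 3 down, 20 adjusted over the list alone), glycolysis (11 of 17 up, 2 down, 13 adjusted over the list alone) and thermogenic genes (7 of 10 up, 1 down, 8 adjusted over the list alone) had camera adjusted p of 0.0196, 0.0292 and 0.00336. With an estimated correlation these were not called (adjusted p = 0.484 with an estimated correlation for the first pair, adjusted p = 0.23 with an estimated correlation for the thermogenic genes). Dynamics was not called with the 3 libraries that stood apart left out, nor was glycolysis after correction for GC content and transcript length.

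Interferon-stimulated genes and genes of the fibroblast state fell in WT cells. Of 34 interferon response genes 32 fell and 1 rose (33 adjusted over the list alone, median log2 fold change -3.48, camera adjusted p = 3.93e-19). Ifi44 had no count at day 6, at least 99.3-fold lower, and Ifit3 stood at -8.56 ± 0.29. Of 17 myofibroblast and contractile genes 13 fell and 2 rose (15 adjusted over the list alone, median -2.04, camera adjusted p = 0.000883). Tpm1, for a tropomyosin, was at -3.06. Of 17 preadipocyte markers 12 fell (12 adjusted over the list alone, camera adjusted p = 0.000256, adjusted p = 0.0771 with an estimated correlation). Pdgfrb, for a platelet-derived growth factor receptor, went from 563.2 to 78.61 CPM. Extracellular matrix genes fell in 20 of 33 and rose in 9 (29 adjusted over the list alone, camera adjusted p = 0.000226, adjusted p = 0.385 with an estimated correlation). Tnc was at -4.90 and Timp3 at -4.19. Of 34 cell cycle genes 24 fell and 2 rose (26 adjusted over the list alone, camera adjusted p = 0.00309, adjusted p = 0.118 with an estimated correlation). Mcm2 was at -1.68. Of 16 p53 targets 9 fell and 2 rose (11 adjusted over the list alone, camera adjusted p = 0.00653, adjusted p = 0.0541 with an estimated correlation). Plk2 was at -4.10. Cholesterol synthesis and uptake (11 of 23 up, 3 down, 14 adjusted over the list alone) and the integrated stress response (10 of 26 up, 6 down, 16 adjusted over the list alone) were not called. Neither were insulin signalling (11 of 21 up, 6 down, 17 adjusted over the list alone, called higher without WT day 0 replicate 3 or WT day 6 replicate 2) and chemokines and acute phase genes (7 of 17 up, 9 down, 16 adjusted over the list alone). The chemokine and acute phase list had a negative median and mean and a test in the direction of a rise: Cxcl5 was at -6.58 and Lcn2 at 7.60. In all, 7956 of 12279 genes changed, 3890 up and 4066 down (edgeR quasi-likelihood, adjusted p under 0.05), and 22 of 31 lists. The cell cycle call was not kept with the 3 libraries that stood apart left out.

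**Figure D2:**
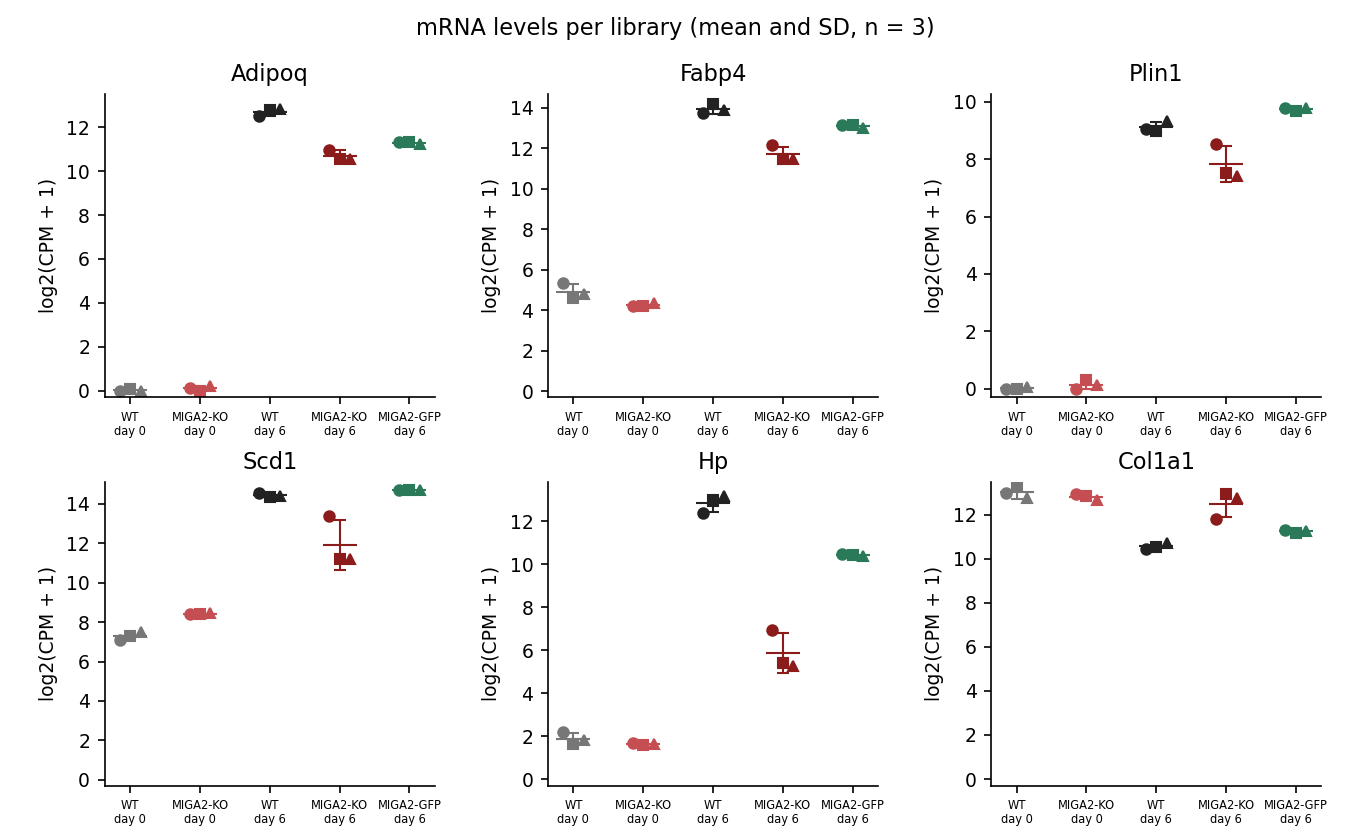
Log2(CPM + 1) of Adipoq, Fabp4, Plin1, Scd1, Hp and Col1a1, 1 point per library, with the mean and SD of each group of 3. Adipoq lies near 0 in all day 0 libraries and highest in WT at day 6, at a mean of 6751 CPM.

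MIGA2-KO cells also induced fat cell genes. Adipoq rose from 0.0808 to 1671 ± 311 CPM (SD, n = 3), a ratio of 21100 with a 95% counting interval of 7200 to 102000. Cfd rose at least 13700-fold, Cidec, a lipid droplet protein, at least 2380-fold, and Fabp4 from 17.99 to 3371 ± 966 CPM. Of the adipocyte markers and adipokines 19 of 20 rose (19 adjusted over the list alone), with a median log2 fold change of 7.43, 5.47 with genes at 0 set to their bound, and 5.72 without the library labelled MIGA2-KO day 6 replicate 1 (camera adjusted p = 6.25e-33). Pparg rose from 26.46 to 158.2 ± 4.08 CPM (log2 fold change 2.58 ± 0.087, adjusted p = 2.36e-11 in edgeR quasi-likelihood) and Cebpa from 0.529 to 30.62 ± 8.85 CPM (5.83 ± 0.30, and 6.56 without MIGA2-KO day 0 replicate 1). The regulators rose as a list, with 11 of 19 up and 3 down (15 adjusted over the list alone, median 1.08, camera adjusted p = 4.71e-06). Lipolysis genes rose too, with 15 of 17 up and 1 down (16 adjusted over the list alone, median 5.73, 4.51 with bounds and 4.69 without the library labelled MIGA2-KO day 6 replicate 1, camera adjusted p = 3.3e-19). Triacylglycerol synthesis (14 of 21 up, 1 down, 16 adjusted over the list alone) and lipid droplet proteins (10 of 18 up, 2 down, 12 adjusted over the list alone) had camera adjusted p of 1.86e-07 and 2.62e-06. With an estimated correlation neither held, at adjusted p = 0.0698 with an estimated correlation for the former and adjusted p = 0.0652 with an estimated correlation for the latter. De novo lipogenesis was not called (9 of 23 up, 5 down, 14 adjusted over the list alone) but was called higher without MIGA2-KO day 6 replicate 2 or replicate 3, and Acly, for ATP citrate lyase, fell by 1.25 ± 0.13.

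Mitochondrial genes rose less broadly in MIGA2-KO than in WT cells, and cholesterol genes fell. Of the TCA cycle genes 24 of 25 rose (25 adjusted over the list alone, median 0.85, camera adjusted p = 3.51e-13). Of the peroxisomal genes 22 of 32 rose and 1 fell (25 adjusted over the list alone, median 0.73, camera adjusted p = 1.86e-08). Fatty acid oxidation rose in 17 of 21 genes and fell in 1 (19 adjusted over the list alone, camera adjusted p = 9.77e-08, adjusted p = 0.0771 with an estimated correlation). The nuclear respiratory chain rose in 51 of 75 (56 adjusted over the list alone, median 0.77, camera adjusted p = 1.07e-06, adjusted p = 0.615 with an estimated correlation). Cholesterol synthesis and uptake fell in 18 of 23 genes (18 adjusted over the list alone, median -1.19, camera adjusted p = 9.25e-08). Lss, for lanosterol synthase, was at a log2 fold change of -1.51 ± 0.12, Sqle at -1.47 and the regulator Srebf2 at -1.21. All 34 interferon response genes fell (34 adjusted over the list alone, median -3.69, camera adjusted p = 2.23e-55). Ifit1 was at -6.52 ± 0.19. Myofibroblast genes fell in 13 of 17 and rose in 2 (15 adjusted over the list alone, median -1.51, camera adjusted p = 0.000162). The p53 targets fell in 12 of 16 and rose in 1 (13 adjusted over the list alone, median -0.93, camera adjusted p = 0.000439). Preadipocyte markers fell in 8 of 17 and rose in 2 (10 adjusted over the list alone, camera adjusted p = 0.00236, adjusted p = 0.116 with an estimated correlation). Pdgfrb was at -1.36 ± 0.090.

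Weaker list results in MIGA2-KO over time were rises in mitochondrial chaperones (10 of 14 up, 1 down, 11 adjusted over the list alone, camera adjusted p = 0.0201) and thermogenic genes (9 of 10 up, 9 adjusted over the list alone, camera adjusted p = 0.00304). Insulin signalling (10 of 21 up, 3 down, 14 adjusted over the list alone, camera adjusted p = 0.0393) and the unfolded protein response (11 of 25 up, 1 down, 12 adjusted over the list alone, camera adjusted p = 0.0491) rose as well. The first pair was lost at adjusted p = 0.406 with an estimated correlation and adjusted p = 0.23 with an estimated correlation. The other pair was lost at adjusted p = 0.569 with an estimated correlation for insulin signalling and adjusted p = 0.571 with an estimated correlation for the unfolded protein response. The chaperone and unfolded protein response calls were not kept without the library labelled MIGA2-KO day 6 replicate 1 or after the GC content and length correction, nor the insulin call without MIGA2-KO day 0 replicate 1. Leaving out the last gave 16 called lists in place of 18, so the insulin call was not the sole one lost there. The thermogenic median, 4.08, was 2.54 without the library labelled MIGA2-KO day 6 replicate 1. Mitochondrially encoded mRNAs (5 of 8 up, 5 adjusted over the list alone), mitochondrial dynamics (11 of 31 up, 10 adjusted over the list alone), glycolysis (5 of 17 up, 6 down) and the cell cycle (8 of 34 up, 4 down) were not called. Extracellular matrix genes were not called either (14 of 33 up, 9 down, 24 adjusted over the list alone), with a positive median and mean and a test in the direction of a fall: Lum, for the collagen-binding protein lumican, rose by 4.43 and Col12a1 fell by 5.14. In all, 5442 genes changed, 2862 up and 2580 down (edgeR quasi-likelihood, adjusted p under 0.05), and 18 of 31 lists. Of these genes 2250 rose in both lines, against 907 if calls in the lines were independent, 2049 fell in both, against 854, while 61 rose in WT and fell in MIGA2-KO and 106 did the reverse.

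The change from day 0 to day 6 differed between the lines for 3346 genes, 1678 with a more positive and 1668 with a more negative change over time in MIGA2-KO (edgeR quasi-likelihood interaction, adjusted p under 0.05). Without WT day 0 replicate 1 the count was 5186. Pparg had a change smaller by -1.76 ± 0.12 on the log2 scale (adjusted p = 2.21e-07, edgeR), Fasn by -2.79 ± 0.18 and Nr1h3, for the liver X receptor alpha, by -3.04. De novo lipogenesis was lower in 17 of 23 genes and higher in 1 (19 adjusted over the list alone, median -1.4, camera adjusted p = 3.02e-13). Cholesterol synthesis and uptake was lower in 19 of 23 (20 adjusted over the list alone, median -1.55, camera adjusted p = 3.35e-20). Nsdhl, of sterol synthesis, was at -2.26 ± 0.14 and Lss at -1.98. Fatty acid oxidation was lower in 18 of 21 genes and higher in 1 (20 adjusted over the list alone, median -1.12, camera adjusted p = 8.42e-12). TCA cycle genes were lower in 21 of 25 (22 adjusted over the list alone, median -0.9, camera adjusted p = 8.66e-15) and peroxisomal genes in 20 of 32 (22 adjusted over the list alone, median -0.73, camera adjusted p = 1.01e-07). Adipocyte markers were lower in 10 of 20 genes (12 adjusted over the list alone, median -2.27, camera adjusted p = 2.17e-09, adjusted p = 0.133 with an estimated correlation). Apmap, for an adipocyte membrane protein, was at -2.57. The nuclear respiratory chain was lower in 48 of 75 genes (61 adjusted over the list alone, median -1.01, camera adjusted p = 8.86e-15, adjusted p = 0.385 with an estimated correlation).

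Cell cycle and matrix genes went the other way, with a more positive change in MIGA2-KO. Of 34 cell cycle genes 19 had the higher change and 1 the lower (28 adjusted over the list alone, median 1.08, camera adjusted p = 4.03e-08). The replication licensing gene Mcm3 was at 1.58 and the cyclin gene Ccna2 at 1.91. Extracellular matrix genes were higher in 15 of 33 and lower in 3 (19 adjusted over the list alone, median 0.74, camera adjusted p = 1.08e-10, adjusted p = 0.139 with an estimated correlation). Dcn, for decorin, was at 3.50 ± 0.16 and Postn, for periostin, at 2.42. The preadipocyte markers Pdgfrb, at 1.48 ± 0.13, and Prrx1, at 1.79, were among 5 of 17 that were higher (5 adjusted over the list alone, camera adjusted p = 0.0211, adjusted p = 0.23 with an estimated correlation). Ppargc1a, for the coactivator PGC-1 alpha, was at 3.24 ± 0.47.

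MIGA2-KO and WT cells already differed when the differentiation medium was added. At day 0 MIGA2-KO cells had more interferon-stimulated mRNA: 28 of 34 genes were higher (28 adjusted over the list alone, median log2 fold change 1.02, camera adjusted p = 7.55e-23). Oas3, for an antiviral 2'-5' oligoadenylate synthetase (ENSMUSG00000032661, chromosome 5: 120753098 to 120777661, reverse strand), was at 6.789 ± 0.771 against 0.4244 CPM (4.00 ± 0.40, adjusted p = 2.25e-05 in edgeR quasi-likelihood). Ifit1 was at 165.6 ± 1.5 against 64.11 ± 5.49 CPM. Cell cycle genes were lower in 25 of 34 and higher in 2 (30 adjusted over the list alone, median -0.94, camera adjusted p = 9.75e-11). The mitotic genes Cenpa and Bub1b were at -2.04 and -1.42. Among the adipogenic regulators, Pparg was higher by 0.87 ± 0.086 and Cebpa lower, at -3.40 ± 0.33 and -4.12 without MIGA2-KO day 0 replicate 1. The list of regulators was not called (4 of 19 up, 1 down). The matrix genes Dcn (33.45 against 265.2 CPM) and Lum (ENSMUSG00000036446, chromosome 10: 97565128 to 97572703, forward strand; 0.8458 against 31.45 CPM) were lower, without a call for the matrix list (8 of 33 up, 8 down), which was called lower without WT day 0 replicate 1. Among the largest differences were also Ptprq, a receptor phosphatase gene, at 3.66 ± 0.19, Galnt15 at 3.28, and Elfn1 at 3.24. Lower were Socs2, for a suppressor of cytokine signalling, at -5.24 ± 0.22, Rgs16 at -4.70 and Sema7a at -4.45.

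The other lists called at day 0 were not called with an estimated correlation. Mitochondrially encoded mRNAs were higher in 6 of 8 (7 adjusted over the list alone, camera adjusted p = 4.22e-05, adjusted p = 0.137 with an estimated correlation). mt-Nd2 was at 1.70 ± 0.18. The nuclear respiratory chain was lower in 30 of 75 genes and higher in 1 (36 adjusted over the list alone, median -0.57, camera adjusted p = 4.46e-05, adjusted p = 0.676 with an estimated correlation). This call was not kept without WT day 0 replicate 1 or after correction for GC content and length. Targets of the integrated stress response were lower in 11 of 26 and higher in 1 (12 adjusted over the list alone, camera adjusted p = 0.000226, adjusted p = 0.362 with an estimated correlation). The proline synthesis genes Pycr1 and Aldh18a1 were at -1.38 and -0.83. Cholesterol genes were higher in 10 of 23 and lower in 1 (12 adjusted over the list alone, camera adjusted p = 0.00314, adjusted p = 0.245 with an estimated correlation). Lipogenesis (6 of 23 up, 2 down, 10 adjusted over the list alone) and insulin signalling (7 of 21 up, 1 down, 8 adjusted over the list alone) were higher, with camera adjusted p of 0.0324 and 0.0336. These were lost at adjusted p = 0.553 with an estimated correlation for lipogenesis and adjusted p = 0.56 with an estimated correlation for insulin signalling. The lipogenesis call was not kept without WT day 0 replicate 3, nor the insulin call under most alternatives. Glycolysis was lower in 7 of 17 genes and higher in 1 (10 adjusted over the list alone, camera adjusted p = 0.0318, adjusted p = 0.484 with an estimated correlation). That call was not kept without WT day 0 replicate 1 or after the same correction. In all, 4159 genes differed at day 0, 1981 higher and 2178 lower in MIGA2-KO (edgeR quasi-likelihood, adjusted p under 0.05), and 9 of 31 lists.

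Genes on chromosome 8 were lower as a whole in MIGA2-KO. Of 675 tested genes there, 371 were lower and 20 higher at day 0, and 388 were lower and 65 higher at day 6. The chromosome median relative to all genes was -0.531 at day 0 and -0.589 at day 6, and -0.2 in MIGA2-GFP against WT, while no other chromosome lay farther than 0.214 from the median of all genes at day 0. At day 6 other chromosomes lay farther out too, with chromosome 3 at 0.337, chromosome 4 at -0.32 and chromosome X at 0.301. Genes of chromosome 8 named for MIGA2-KO against WT are therefore given with it.

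**Figure D3:**
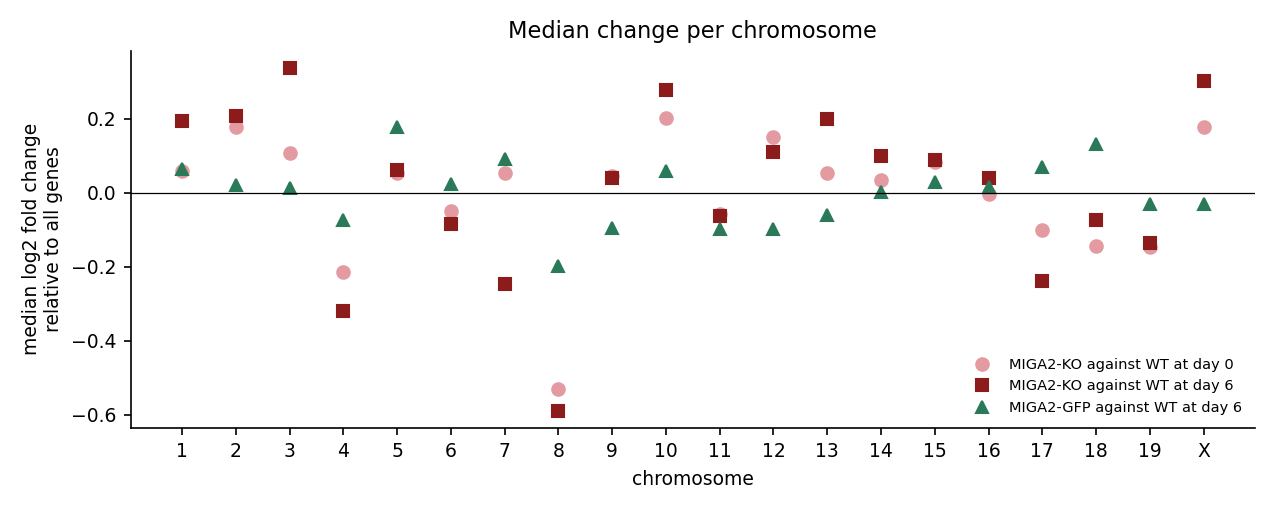
Median log2 fold change of the tested genes of each chromosome relative to all genes, for MIGA2-KO against WT at day 0 and day 6 and MIGA2-GFP against WT at day 6. Chromosome 8 lies at -0.531 and -0.589 in MIGA2-KO.

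At day 6 MIGA2-KO cells held less mRNA of cholesterol synthesis, fatty acid oxidation, TCA cycle and peroxisomal genes than WT cells. Of the adipocyte markers and adipokines 17 of 20 were lower (18 adjusted over the list alone, median log2 fold change -2.21, camera adjusted p = 3.65e-12, adjusted p = 0.0656 with an estimated correlation). The ratio of MIGA2-KO to WT had a median of 21.6% over the 18 members that rose at least 16-fold in WT: 24.7% for Adipoq, 21.4% for Fabp4, 11.3% for Cfd, 2.87% for Retn (1.56% without the library labelled MIGA2-KO day 6 replicate 1) and 89.8% for the amine oxidase gene Aoc3. Retn and Lpl (34.3%) lie on chromosome 8, whose genes were lower as a whole. Cebpa was at 30.62 against 209.4 CPM (-2.77 ± 0.20, adjusted p = 7.91e-08 in edgeR quasi-likelihood) and Pparg at 158.2 against 294.8 CPM (-0.90 ± 0.082). The list of regulators was not called (6 of 19 up, 9 down, 15 adjusted over the list alone). Among the largest decreases were those of Csn2, for a casein (ratio 0.00512, 95% counting interval 0.000617 to 0.0186, and a fitted log2 fold change of -7.40 with all libraries and -10.34 without the library labelled MIGA2-KO day 6 replicate 1), Aldh1l1, for a folate enzyme (1.635 ± 1.53 against 232.9 ± 38.7 CPM; log2 fold change -7.16 ± 0.36, and -8.23 without the library labelled MIGA2-KO day 6 replicate 1), Cyp2b10 at -7.00 ± 0.24, and Hp, for haptoglobin (ENSMUSG00000031722, chromosome 8: 109575128 to 109579172, reverse strand). Hp was at 66.77 ± 48 against 7450 ± 1960 CPM, -6.80 ± 0.44 with all libraries and -7.57 without the library labelled MIGA2-KO day 6 replicate 1, far below the median of its chromosome.

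Lipid and mitochondrial genes were lower at day 6 as follows. Of 23 cholesterol genes 16 were lower (16 adjusted over the list alone, median -1.12, camera adjusted p = 4.4e-08), led by Nsdhl at -2.09 ± 0.099. Fatty acid oxidation was lower in 20 of 21 genes and higher in 1 (21 adjusted over the list alone, median -1.24, camera adjusted p = 6.11e-11). Acadm was at -1.64 ± 0.083. In the TCA cycle 23 of 25 genes were lower (24 adjusted over the list alone, median -1, camera adjusted p = 1.32e-11). Mpc1, for a subunit of the mitochondrial pyruvate carrier, was at -1.75. Peroxisomal genes were lower in 21 of 32 and higher in 4 (26 adjusted over the list alone, median -0.86, camera adjusted p = 9.74e-07). The nuclear respiratory chain was lower in 74 of 75 genes (74 adjusted over the list alone, median -1.57, camera adjusted p = 1.54e-19, adjusted p = 0.329 with an estimated correlation). Its median was -0.73 after correction for GC content and length. De novo lipogenesis was lower in 19 of 23 genes and higher in 2 (21 adjusted over the list alone, camera adjusted p = 5.8e-07, adjusted p = 0.139 with an estimated correlation). Fasn was at -2.08 ± 0.13. Lipolysis was lower in 14 of 17 genes (15 adjusted over the list alone, camera adjusted p = 7.71e-06, adjusted p = 0.143 with an estimated correlation). Mgll, for monoglyceride lipase, was at -3.20. Triacylglycerol synthesis was lower in 14 of 21 and higher in 3 (17 adjusted over the list alone, camera adjusted p = 0.00216, adjusted p = 0.23 with an estimated correlation). Agpat2 was at -1.80. Glycolysis was lower in 15 of 17 and higher in 1 (16 adjusted over the list alone, median -1.49, camera adjusted p = 1.24e-07, adjusted p = 0.079 with an estimated correlation). The glycolysis median was -0.96 after the same correction. Ldha, for lactate dehydrogenase, was at -2.19. Mitochondrial chaperones were lower in 14 of 14 (14 adjusted over the list alone, camera adjusted p = 7.84e-05, adjusted p = 0.159 with an estimated correlation). Clpx was at -1.45. Lipid droplet proteins (12 of 18 lower, 3 higher, 15 adjusted over the list alone) and the integrated stress response (14 of 26 lower, 14 adjusted over the list alone) had camera adjusted p of 0.0128 and 0.00104. They were lost at adjusted p = 0.242 with an estimated correlation for the former and adjusted p = 0.388 with an estimated correlation for the latter. Neither call was kept after the GC content and length correction. Within them Cidec was at -4.61 ± 0.24 and the folate enzyme gene Mthfd2 at -3.02 ± 0.17.

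The matrix and interferon lists were the 2 called higher in MIGA2-KO at day 6. Extracellular matrix genes were higher in 20 of 33 and lower in 6 (28 adjusted over the list alone, camera adjusted p = 2.74e-05, adjusted p = 0.348 with an estimated correlation). Postn was at 2572 ± 468 against 591.7 ± 108 CPM and the membrane collagenase gene Mmp14 at 1.84 ± 0.12. Interferon genes were higher in 19 of 34 and lower in 5 (24 adjusted over the list alone, median 1.16, 1.05 with bounds, camera adjusted p = 0.00137). That call was not kept with the 3 libraries that stood apart left out. Ifit1 had a ratio of 28.4 (95% counting interval 7.53 to 239). Pdgfrb was at 1.65 ± 0.092 and Prrx1 at 1.75, in a preadipocyte list that was not called (7 of 17 up, 3 down, camera adjusted p = 0.0683) but was called higher without the library labelled MIGA2-KO day 6 replicate 1 and after the GC content and length correction. Thermogenic genes were not called (2 of 10 up, 6 down, 8 adjusted over the list alone, median -1.67), but were called lower, with a median of -3.06, without the library labelled MIGA2-KO day 6 replicate 1. Other single genes that were higher were the aldo-keto reductase gene Akr1c14 (98.7 ± 19 against 4.446 CPM), the thyroid hormone receptor gene Thrb at 3.94, Ppargc1a at 2.78 ± 0.36, and the chemokine gene Cxcl12 at 2.24. Mitochondrially encoded mRNAs (3 of 8 lower), mitochondrial dynamics (6 of 31 up, 13 down, called lower after the GC content and length correction), the unfolded protein response (6 of 25 up, 9 down) and the cell cycle (11 of 34 up, 6 down) were not called. Myofibroblast genes (8 of 17 up, 2 down) and chemokines and acute phase genes (7 of 17 up, 6 down) were not called, each with a positive median and a negative mean. In all, 7452 genes differed, 3581 higher and 3871 lower in MIGA2-KO (edgeR quasi-likelihood, adjusted p under 0.05), and 15 of 31 lists. Of these, 1251 were higher at both days (578 if independent), 1323 lower at both (687), 183 higher at day 0 and lower at day 6, and 176 the reverse. After correction for GC content and length 131 genes were called in the opposite direction.

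**Figure D4:**
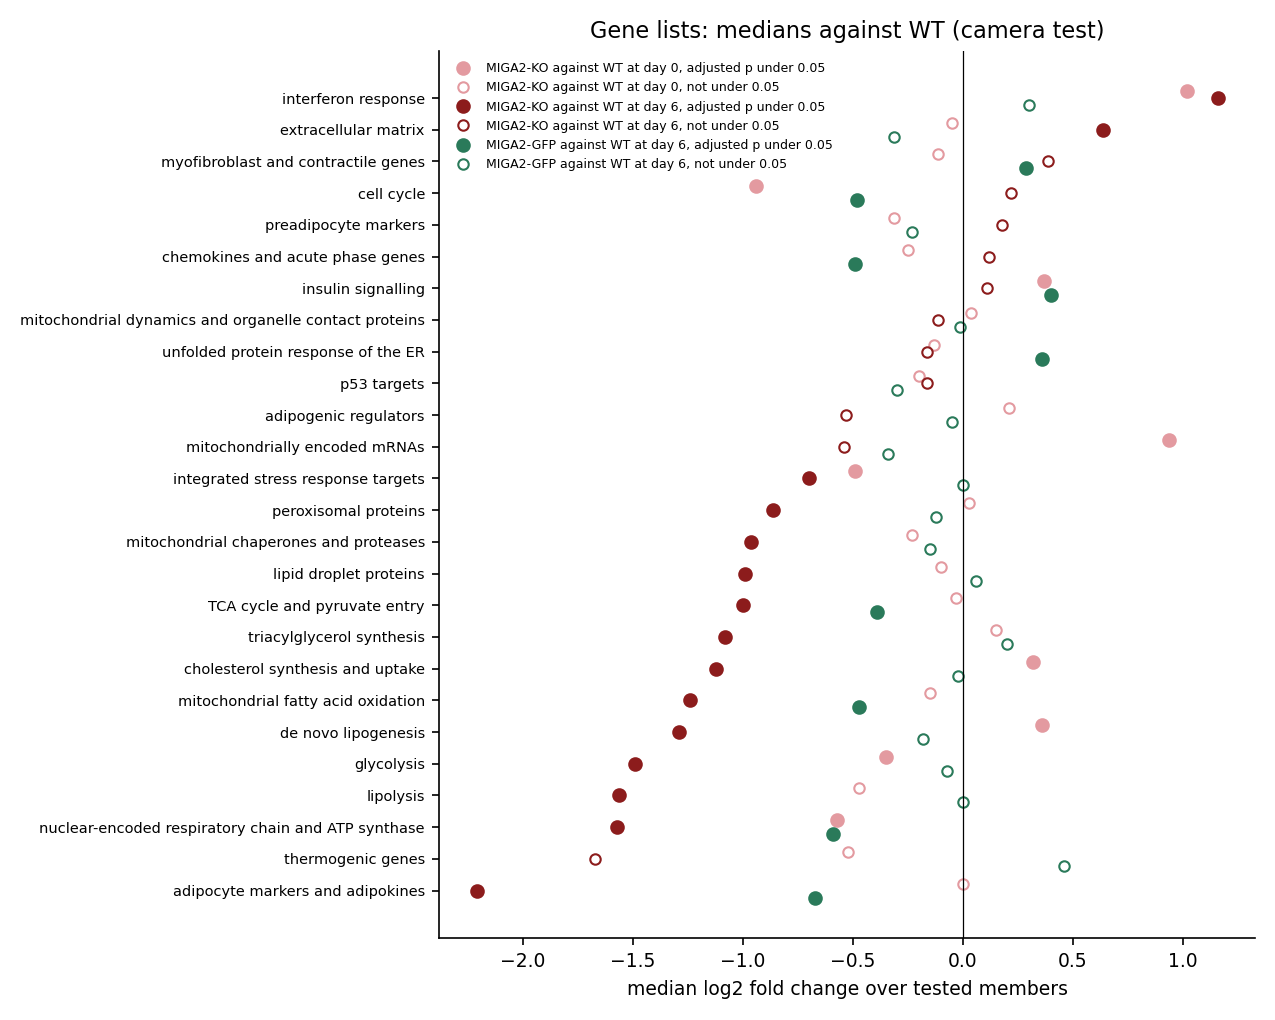
Median log2 fold change of each gene list for MIGA2-KO against WT at day 0 and day 6 and for MIGA2-GFP against WT at day 6. Filled points are lists with a camera adjusted p under 0.05, and the adipocyte markers lie at -2.21 in MIGA2-KO and -0.67 in MIGA2-GFP at day 6.

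MIGA2-GFP cells had lower mRNA of 11 of 20 adipocyte genes than WT cells at day 6. Adipoq was at 2518 ± 57 against 6751 ± 831 CPM (SD, n = 3; log2 fold change -1.42 ± 0.18, adjusted p = 6.88e-05 in edgeR quasi-likelihood), Lep, for leptin, at 0.111 against 4.058 CPM (-5.06 ± 0.50), and Pparg at -0.64 ± 0.081. For the list of adipocyte markers, with 11 of 20 lower, the call was lost with an estimated correlation (12 adjusted over the list alone, median -0.67, camera adjusted p = 4.22e-05, adjusted p = 0.305 with an estimated correlation). Not all genes of the fat cell were lower. Plin1, outside this list, was at 828.3 to 883.4 CPM in the MIGA2-GFP libraries against 501.1 to 641.5 in WT at day 6. Scd1, of the lipogenesis list, was at 26870 to 27270 against 21000 to 24370 CPM. Hp was at 1376 ± 55.7 against 7450 ± 1960 CPM and the complement gene C3 at -0.97 ± 0.099. Chemokines and acute phase genes were lower in 8 of 17 and higher in 3 (13 adjusted over the list alone, camera adjusted p = 0.00646, adjusted p = 0.174 with an estimated correlation). The nuclear respiratory chain was lower in 44 of 75 genes (52 adjusted over the list alone, median -0.59, camera adjusted p = 2.93e-08, adjusted p = 0.559 with an estimated correlation). Its median was -0.18 after correction for GC content and length. Cox7b, of complex IV, was at -1.50 ± 0.18. TCA cycle genes were lower in 15 of 25 (18 adjusted over the list alone, camera adjusted p = 0.000136, adjusted p = 0.0589 with an estimated correlation). Fatty acid oxidation was lower in 12 of 21 and higher in 1 (13 adjusted over the list alone, camera adjusted p = 0.00184, adjusted p = 0.278 with an estimated correlation). Cell cycle genes were lower in 16 of 34 and higher in 2 (19 adjusted over the list alone, camera adjusted p = 0.00901, adjusted p = 0.158 with an estimated correlation). That call was not kept with the 3 libraries that stood apart left out.

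The unfolded protein response was higher in MIGA2-GFP. Of its 25 genes 12 were higher and 3 lower (16 adjusted over the list alone, median 0.36, camera adjusted p = 0.00535, adjusted p = 0.399 with an estimated correlation). The stress sensor genes Ern1, for IRE1, and Eif2ak3, for PERK, were at 1.84 ± 0.22 and 0.93. Insulin signalling was higher in 4 of 21 genes and lower in 1 (5 adjusted over the list alone, camera adjusted p = 0.0119, adjusted p = 0.484 with an estimated correlation). Myofibroblast genes were higher in 6 of 17 and lower in 2 (9 adjusted over the list alone, camera adjusted p = 0.0294, adjusted p = 0.132 with an estimated correlation), and not called without WT day 6 replicate 1. Among the largest increases of genes with at least 5 CPM were Lama5, for a laminin chain (ENSMUSG00000015647, chromosome 2: 180176373 to 180225859, reverse strand), at 31.99 ± 1.46 against 2.604 CPM (3.62 ± 0.47), Plekha6 at 2.96, Gpr35 at 2.46, and Lmod1, for a leiomodin, at 2.22 ± 0.18. Among those lower were Upk2, for a uroplakin (ENSMUSG00000041523, chromosome 9: 44452715 to 44454976, reverse strand), at 0.3649 against 20.51 CPM (-5.77 ± 0.37), Retnla at -5.48 ± 0.35 (-6.31 without MIGA2-GFP day 6 replicate 2), the zinc transporter gene Slc39a4 at -5.39, and Upk3b at -4.26. Lists for regulators (1 of 19 up, 5 down), lipogenesis (3 of 23 up, 7 down), triacylglycerol synthesis (5 of 21 up, 1 down), cholesterol (4 of 23 up, 4 down), matrix (4 of 33 up, 14 down, camera adjusted p = 0.0554, called lower after the GC content and length correction) and interferon (7 of 34 up, 5 down) were not called. In all, 4338 genes differed, 2020 higher and 2318 lower (edgeR quasi-likelihood, adjusted p under 0.05), and 9 of 31 lists, 0 of which were called by camera with an estimated correlation (3 lists had an unadjusted p under 0.05 there, and fry called 15). Without WT day 6 replicate 2 the count of genes was 2759.

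Many genes differed from WT at day 6 in both MIGA2-KO and MIGA2-GFP. Of the genes called in both comparisons 1234 were higher in both, 1573 were lower in both, and 167 higher and 149 lower in MIGA2-KO went the opposite way in MIGA2-GFP. The correlation of the log2 fold changes across genes was 0.523. Both comparisons use the same 3 WT libraries, which by itself raises the number of shared calls, and shared calls were not simulated. For the correlation, simulated data in which only these were shared gave a median correlation of 0.521 (0.482 to 0.56 over 50 simulations). Without any effect, shared libraries set the correlation near this value whatever the size of the fold changes. The correlation therefore cannot tell a shared effect from the shared libraries. The covariance, which keeps the size of the fold changes, was 0.441 against a simulated median of 0.05 and a simulated maximum of 0.056. The shared libraries as simulated thus did not reach it. The covariance was 0.746 without WT day 6 replicate 1 and 0.307 for genes with at least 10 CPM.

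Markers of other cell types moved with the groups without a call for any of their lists with all libraries in. The osteoblast markers summed to 901 ± 71.3 CPM (SD, n = 3) in WT at day 0, of which Spp1, for osteopontin, made up 864, and to 51.3 ± 3.34 at day 6, with Spp1 at 38.3. In MIGA2-KO they summed to 532 ± 9.22 and 59 ± 38.9 CPM, and Spp1 over time went from a log2 fold change of -3.95 to -5.59 without the library labelled MIGA2-KO day 6 replicate 1. The macrophage markers summed to 103 ± 19.9 and 29.5 ± 5.23 CPM in WT, with the lysozyme gene Lyz2 at 81 and 10.4. They summed to 94.4 ± 1.28 and 39.2 ± 4.63 CPM in MIGA2-KO, and to 33.8 ± 0.624 CPM in MIGA2-GFP. Skeletal muscle markers summed to 16 ± 4.1 and 32 ± 7.64 CPM in WT, 10.5 ± 0.366 and 38.1 ± 25.6 CPM in MIGA2-KO, and 53.3 ± 3.15 CPM in MIGA2-GFP. The MIGA2-KO value at day 6 rests on replicate 3: without it the list median went from 1.1 to -2.14 against WT and from 2.38 to 0.48 over time. Chondrocyte markers, mainly Col11a1, summed to 55.2 ± 19.4 and 18.9 ± 5.8 CPM in WT, 55.9 ± 1.73 and 61.9 ± 17.7 CPM in MIGA2-KO, and 24.2 ± 1.96 CPM in MIGA2-GFP. Epithelial markers had means of at most 9.17 CPM and endothelial markers of at most 8.71 CPM in the 5 groups.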

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

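Tests written after the result was seen were those of the Miga2 level in the library labelled MIGA2-KO day 6 replicate 1 and the GC content and length test on chromosome 8. The change over time differed between MIGA2-KO and WT cells by the interaction test for 3346 genes, for 18 lists and for the named genes with the largest differences. The list medians not yet given were lower in MIGA2-KO for triacylglycerol synthesis (-0.87, 9 of 21 genes, 12 adjusted over the list alone, adjusted p = 0.144 with an estimated correlation), lipolysis (-0.7, 6 of 17, 6 adjusted over the list alone, adjusted p = 0.385 with an estimated correlation), mitochondrially encoded mRNAs (-1.5, 5 of 8, 7 adjusted over the list alone, adjusted p = 0.0936 with an estimated correlation), mitochondrial chaperones (-0.79, and -0.49 after the GC content and length correction, 9 of 14, 10 adjusted over the list alone, adjusted p = 0.162 with an estimated correlation) and glycolysis (-0.96, 13 of 17, 15 adjusted over the list alone, adjusted p = 0.137 with an estimated correlation). Mitochondrial dynamics (-0.36, 10 of 31 lower, 13 adjusted over the list alone, adjusted p = 0.0851 with an estimated correlation), adipogenic regulators (-0.65, 6 of 19 lower, 11 adjusted over the list alone, adjusted p = 0.127 with an estimated correlation) and lipid droplet proteins (-0.7, 6 of 18 lower, 7 adjusted over the list alone, adjusted p = 0.381 with an estimated correlation) were called too. Of these, the regulators and lipid droplet calls each were lost under several alternatives, and that of dynamics with 3 libraries left out. The other medians were -2.27 for adipocyte markers, -1.4 for lipogenesis, -1.55 for cholesterol, -1.12 for fatty acid oxidation, -0.9 for the TCA cycle, -1.01 for the respiratory chain, -0.73 for peroxisomes, 0.21 for preadipocyte markers, 0.74 for matrix and 1.08 for the cell cycle.

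Among named genes whose change over time was more positive in MIGA2-KO, the fitted differences were 5.49 for Lum, 5.33 for Rgs16, 4.88 for Ifit3b, 4.83 for the keratin gene Krt13, 4.71 for Sema7a, 4.45 for Tnr, 4.32 for Spon2 and 4.26 for the stanniocalcin gene Stc1. Lum went from 31.45 to 15.07 CPM in WT and from 0.846 to 18.36 in MIGA2-KO, and Spon2 from 38.12 to 11.72 and from 21.11 to 130. More negative differences were -9.17 for the adenosine receptor gene Adora1, -8.44 for Retnla, -7.91 for Ifi208, -7.15 for Aldh1l1, -6.52 for the transferrin gene Trf, -6.45 for Hp and -5.99 for the hemopexin gene Hpx. Aldh1l1 went from 0.619 to 232.9 CPM in WT and from 0.635 to 1.635 in MIGA2-KO, and Hp, on chromosome 8, from 2.733 to 7450 and from 2.114 to 66.77. Adora1, Retnla and Ifi208 had at most 6 counts at day 0 in WT and reached 7.686, 25.34 and 23.02 CPM at day 6, against 0.087, 0.284 and 0.368 in MIGA2-KO, so their fitted values, like that of Ifit3b with 1 count in WT at day 6, depend on the prior count. Without the library labelled MIGA2-KO day 6 replicate 1 the values were 4.06 for Rgs16, 3.91 for Sema7a, 3.58 for Stc1, -10.07 for Adora1, -8.23 for Aldh1l1, -7.22 for Hp and -8.62 for Hpx. Ifit3b was at 7.12 without WT day 6 replicate 2, Krt13 at 4.17 and Hpx at -6.62 without WT day 0 replicate 1, and Trf at -5.23 without MIGA2-KO day 0 replicate 2. Retnla was not called without MIGA2-KO day 0 replicate 1 (-6.42) or MIGA2-KO day 6 replicate 3, nor Hpx without MIGA2-KO day 0 replicate 1.

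Among 100 splits of the 12 libraries, 4, the real one included, gave at least 3346 genes with a difference between lines. This share is just under 0.05, the bound set for excluding chance, but chance is not excluded by it. The share depends on how many of the drawn splits kept the day 6 groups intact. Those splits still hold the difference between the lines at day 6. The other 3 gave 4436, 5259 and 5827 genes, and each kept the day 6 groups intact, which points to a structure of the samples. For the 18 lists 10 of 100 splits gave as many, with up to 20, so chance was not excluded. Regrouped libraries can still hold a part of the real difference, so these list counts cannot decide the question. For the 5 comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real and highest other counts of genes were 7956 and 3296 for WT over time, 5442 and 0 for MIGA2-KO over time, 4159 and 0 for MIGA2-KO against WT at day 0, 7452 and 0 at day 6, and 4338 and 0 for MIGA2-GFP, with 1 split of 10 as large in each. For lists these were 22 and 20 (1 of 10), 18 and 20 (7 of 10), 9 and 9 (3 of 10), 15 and 20 (5 of 10), and 9 and 6 (1 of 10). Each other split keeps 2 libraries of 1 group on a side, so it holds a part of the real difference. In MIGA2-KO over time such splits called 14 to 20 lists with 0 genes. List counts of these splits thus cannot tell chance from that part. The split with 3296 genes joined WT day 6 replicate 1 with WT day 0 replicates 2 and 3, which shared a trend with transcript length.

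The library labelled MIGA2-KO day 6 replicate 1 held 5.09 times the Miga2 level of the highest other library, which argues against RNA of another listed group mixed into it as the source of Miga2. A swap with a MIGA2-GFP library would leave 1 of those out of place, but they correlated at 0.9931 or more with each other and at most 0.9548 with MIGA2-KO at day 6. Tested genes within 100 kb of Miga2 reached at most 0.996 times their level in the other 2 libraries of the group, against extra copies of the region. Chromosome 8 genes lay at -0.47 in this library relative to WT at day 6, against -0.61 in both other MIGA2-KO libraries and -0.19 to -0.22 in MIGA2-GFP, which argues against a wrongly labelled WT or MIGA2-GFP library. Cells of the MIGA2-KO line that express Miga2 again, or a sample from outside the series, may be the source, and neither was tested.

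The lower nuclear respiratory chain mRNAs at day 6 could stem from a trend with GC content and transcript length between libraries, since the members are short (median 754 against 2238 bases for all genes). After the correction the median was -0.73 in MIGA2-KO (95% bootstrap interval -0.87 to -0.65) with 67 genes lower in place of 74, and -0.18 in MIGA2-GFP (-0.25 to -0.11) with 29 in place of 44. Both medians stayed below 0 after the correction, which took away the larger part of both differences. The trend as fitted thus does not account for all of either. The bootstrap resampled genes, which are not independent, and does not measure the spread between libraries. Whether a part of the trend remained after the correction was not tested, so the source of the remainder stays open. At day 0 the MIGA2-KO median went from -0.57 to -0.14 (-0.21 to -0.01) and the call ended because the fold shrank. The correction may also remove true differences, and a biological effect of MIGA2 on these genes remains a hypothesis.

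Fewer copies of chromosome 8 in the MIGA2-KO line are a candidate explanation for part of the genes that differ from WT at both days. The chromosome median at day 0 was -0.531 relative to all genes, beside a log2 ratio of -0.58 for 2 copies against 3 and -0.42 for 3 against 4, and 11 of 11 windows of 10 Mb lay below 0, while at day 6 chromosomes 3, 4 and X, at 0.337, -0.32 and 0.301, set it less apart. A trend with GC content and length was argued against, since the median after the correction was -0.52. Copy number itself was not measured, and an effect of MIGA2 on this chromosome was not tested. Differences between MIGA2-KO and WT on this chromosome thus may not come from MIGA2.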

How the results depend on the processing

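Alternatives chosen after seeing the data were the correction for GC content and length, the 3 libraries left out together, the thinning of WT day 0 and the omission of chromosome 8. Of 755 values of named genes, 63 lost their call or turned under at least 1 alternative and 5 turned. Those that turned without MIGA2-KO day 6 replicate 3 were the muscle genes Tnnt3 (-2.56 to 4.31 over the libraries left out in MIGA2-KO over time, -2.8 to 4.07 against WT at day 6) and Acta1 (-1.48 to 3.26 against WT at day 6), which lies on chromosome 8, whose genes were lower as a whole. Miga2 turned without the library labelled MIGA2-KO day 6 replicate 1, with a range of -1.16 to 1.64 against WT at day 6 and -1.54 to 1.25 in the difference between lines. With the 3 libraries left out it was at -1.22 and -1.59. The difference between lines in Miga2, which had no call, was also -0.31 with limma-voom. The turned values follow from the library left out, and for limma-voom the cause was not tested. Leaving out each library in turn gave 7239 to 8860 genes for WT over time, 4516 to 6221 for MIGA2-KO over time, 2809 to 4801 for MIGA2-KO against WT at day 0, 6456 to 8081 at day 6, 2759 to 5438 for MIGA2-GFP, and 2541 to 5186 for the difference between lines. Lists ranged over 22 to 24, 16 to 19, 7 to 9, 15 to 17, 8 to 10 and 16 to 19, and the correlation between MIGA2-KO and MIGA2-GFP over 0.43 to 0.64. With the 3 libraries left out 7625 genes were called for MIGA2-GFP and 7655 for the difference between lines. Under the other alternatives apart from leaving out single libraries, each count of genes stayed within 1.5 times its value. With an estimated correlation 8, 9, 2, 5, 0 and 6 lists were called, and with fry 25 for MIGA2-KO at day 6 and 15 for MIGA2-GFP. After the GC content and length correction the median of further called lists moved by over 1.5 times: from -0.39 to -0.25 for the TCA cycle and -0.47 to -0.24 for fatty acid oxidation in MIGA2-GFP, from 1.24 to 0.82 for lipid droplet proteins and 0.44 to 0.76 for mitochondrial dynamics in WT over time, and from -0.7 to -0.33 for lipid droplet proteins (call lost) and 0.21 to 0.49 for preadipocyte markers in the difference between lines. Lists not called with all libraries were called by camera under some alternatives. With the GC content and length correction these were lipogenesis in MIGA2-KO and insulin signalling in WT over time, matrix in MIGA2-KO at day 0 and in MIGA2-GFP, and preadipocyte markers and mitochondrial dynamics in MIGA2-KO at day 6. With the 3 libraries left out they were cholesterol in WT and osteoblast markers in both lines over time, matrix and p53 targets in MIGA2-KO at day 0, preadipocyte markers and thermogenic genes at day 6, and chondrocyte markers, the integrated stress response and the unfolded protein response in the difference between lines. Why lists were lost with an estimated correlation was not tested, and fry compares a list with no other genes. With at least 10 CPM the correlation was 0.585 and the covariance 0.307. With a replicate block, although the numbers do not pair the samples, 7578, 5033, 3505, 7078, 3733 and 2790 genes were called. Depth limited the genes near 0 at day 0, where folds are bounds or have wide counting intervals.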

Other observations

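The list of 13 imprinted genes was written after the main results were seen, and values from it are given without an explanation. The genes given were picked after their values were seen. Of the 13, Sgce alone passed neither in MIGA2-KO nor in MIGA2-GFP against WT at day 6. Igf2, for insulin-like growth factor 2, stood at 98.9 CPM in WT at day 6, 19.7 in MIGA2-KO and 19.3 in MIGA2-GFP. Mest stood at 3.51 CPM in WT at day 6, had no count in MIGA2-KO at day 0 or in MIGA2-GFP, and was at 0.029 CPM in MIGA2-KO at day 6. Peg10 was at 260, 512 and 567 CPM in WT, MIGA2-KO and MIGA2-GFP at day 6, and Igf2r, for a receptor that clears IGF2, at 274, 744 and 336 CPM. Sgce was at 91.5, 82.5 and 90.5 CPM and Zrsr1 at 17.4, 15.1 and 13.1 CPM in the same groups.

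The library labelled MIGA2-KO day 6 replicate 1 lay between the other MIGA2-KO libraries and WT at day 6 for most of the genes that set these groups apart. Over 456 such genes its median position was 23% of the way toward WT (10th to 90th percentile 3.96% to 60.7%), and 425 of them, 93.2%, lay above 0. The genes were chosen from the other libraries, which by itself moves a library not used in the choice toward WT.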
